A study of Arabidopsis thaliana with 4 samples.

How the data were processed

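The data were 4 Affymetrix ATH1 arrays, which measure transcript levels with sets of short oligonucleotide probes, hybridised with labelled RNA from dark-grown Arabidopsis thaliana seedlings. The wild type (Columbia) and the phyA phyB double mutant (alleles phyA-211 and phyB-9) each had 2 arrays. Per the labels' protocols, RNA was purified with an RNeasy plant kit and labelled following the array maker's instructions. The deposited values were 1 positive intensity per probe set and array on a linear scale, for 22746 probe sets. The software, the target of the scaling and any detection calls behind these intensities were not given in the sources used here. The values themselves showed that the authors had scaled the arrays before deposit. The mean intensity after trimming 2% at each end differed by 0.0946% between the lowest and highest array, so the deposited scaling was kept. Replicate 1 of the wild type had no replicate number in its label and was numbered by order. No 2 arrays held identical values.

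Intensities were transformed as log2(intensity + 70.1), where the pseudocount was the 10th percentile of all values. Log2 differences are therefore on that scale and understate the change of dim probe sets. The brightest 60% of probe sets by mean over the 4 arrays, 13648 in number, were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method at 0.05. With 2 residual degrees of freedom per probe set, the fit drew on the spread of all probe sets and reached 9.2 in total. The number of arrays limits the precision. An exact permutation of 2 arrays against 2 cannot give a two-sided p under 0.333, so single values were tested only through limma. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

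Gene names came from the platform's annotation, which can be old, updated through the RefSeq table of assembly TAIR10.1. Of the probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed. RefSeq matched 13436 of them, and the others with 1 gene kept the annotation's symbol. Probe sets with several genes or none were not named. No probe set used here was named PHYA, PHYB or ABI3, so the mutated genes could not serve as a check of the genotype labels. No coordinates are given, because no genome build was stated for the files. No genome sequence was used here, so the planned search of promoters for the RY motif was not run. Of the array's hybridisation controls, 0 were in the table, and the planned 3' to 5' quality ratio was not run.

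Before the data were examined, 23 gene lists of 460 genes were fixed. Of these genes, 83 had a named probe set and 70 were tested, each by its brightest probe set. The 5 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over these lists. Another 17 lists, built by chromosome, by gene symbol or from single locus codes, were chosen after the files had been seen and were adjusted separately. Of these, the mitochondrial list was redefined by gene symbol after single genes had been seen. Alternatives were camera with an estimated correlation, and fry.

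Genes were named by a rule fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases among named genes past the threshold whose groups did not overlap. Open places went to genes of at least 2-fold change without overlap, by unadjusted p, and these are given as not past the threshold. From each tested list, the 2 highest and the 2 lowest members by moderated t were also eligible.

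The procedure was tested on simulated data with 13648 probe sets and 200 changed in each of 10 runs. It recovered 0.435% of 2-fold changes, 55.9% of 4-fold changes and 91.8% of 8-fold changes, and 4.22% of its calls were false. Camera found 10 of 10 shifted lists and 0 of the unshifted ones. The simulated genes varied independently, so these runs do not show how camera behaves where the genes of a list vary together. In the data, the estimated correlation ran from 0.14 to 0.96 over the lists of seed genes and was 0.72 for plastid genome genes. The simulated variances were also shuffled over probe sets, without the intensity trend that the fit uses. Each probe set had the same variance in both groups. In the data, the SD of M17 was 0.15 in the wild type and 1.23 in the mutant, and that of psbA 0.59 and 0.26. The recovery and the share of false calls need not hold for such unequal spread. Alternatives covered quantile, median and cyclic loess normalization, other pseudocounts, other filters, other variance models, other thresholds and each array left out. Figures were drawn with matplotlib 3.10.9.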

Results

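The transcript levels of dark-grown seedlings were compared between wild-type Arabidopsis and a mutant lacking phytochromes A and B, the main red and far-red light receptors. Seeds sown on 0.8% agar were chilled for 5 days at 6 °C, given 1 h of white light at 22 °C to start germination, and kept for 3 days in darkness. The design asks how the absence of both receptors changes the transcriptome of seedlings whose only light was that pulse. Each genotype had 2 arrays. Summed intensity per array ranged from 76027250 to 77974921. Across tested probe sets, log2 values correlated at 0.95 between the wild-type arrays and at 0.917 between the mutant arrays. Mutant array 1 stood apart from the wild type, with correlations of 0.90 and 0.886, whereas mutant array 2 had 0.947 and 0.936. These correlations are across probe sets, which are not independent replicates.

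Among named genes, 5 rose and 1 fell in the mutant samples, and M17, PAP85 and AT3G54940 among the 5 belong to lists of seed genes. M17, a late embryogenesis abundant (LEA) protein gene, rose by 3.74 (SE 0.46) on the log2 scale, from 11.94 ± 0.15 to 15.68 ± 1.23 (SD, n = 2 each). PAP85, a vicilin-like seed storage protein gene, rose by 3.29 (SE 0.38). AGL67, a MADS-box gene with wild-type intensities of 112.6 and 328, rose by 4.32 (SE 0.59), a size that ran from 3.42 with the pseudocount at the 25th percentile to 4.79 with none. AT3G54940 rose by 2.66 (SE 0.34). AT1G14930 rose from intensities of 69.2 and 22.2 in the wild type to 8167 and 3534 in the mutant. Its wild-type intensities lay below the pseudocount of 70.1, which sets the size of its log2 difference, 5.59 here and 3.96 with that larger pseudocount. The gene that fell was the plastid-encoded psbA, for the D1 protein of photosystem II, by -2.33 (SE 0.29), from 15.05 ± 0.59 to 12.72 ± 0.26 (SD, n = 2 each). Their adjusted p-values from limma with Benjamini-Hochberg adjustment lay between 0.0062 for AT1G14930 and 0.042 for AGL67, with 0.028 for psbA. Calls ended when arrays were left out (adjusted p from limma): AT1G14930 and AGL67 without mutant array 1 (0.16 and 0.152), AGL67, M17, PAP85 and AT3G54940 without wild-type array 1 (0.0872, 0.0867, 0.0867 and 0.101), and M17, AT3G54940 and psbA without wild-type array 2 (0.0651, 0.143 and 0.21). All 6 calls also ended without the filter on dim probe sets and by eBayes without the trend, those of AGL67 and M17 by robust eBayes (0.0781 and 0.201), and that of AGL67 under quantile normalization (0.0512), without a pseudocount (0.0537) and with the larger one (0.0548), each with the direction kept.

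**Figure D1:**
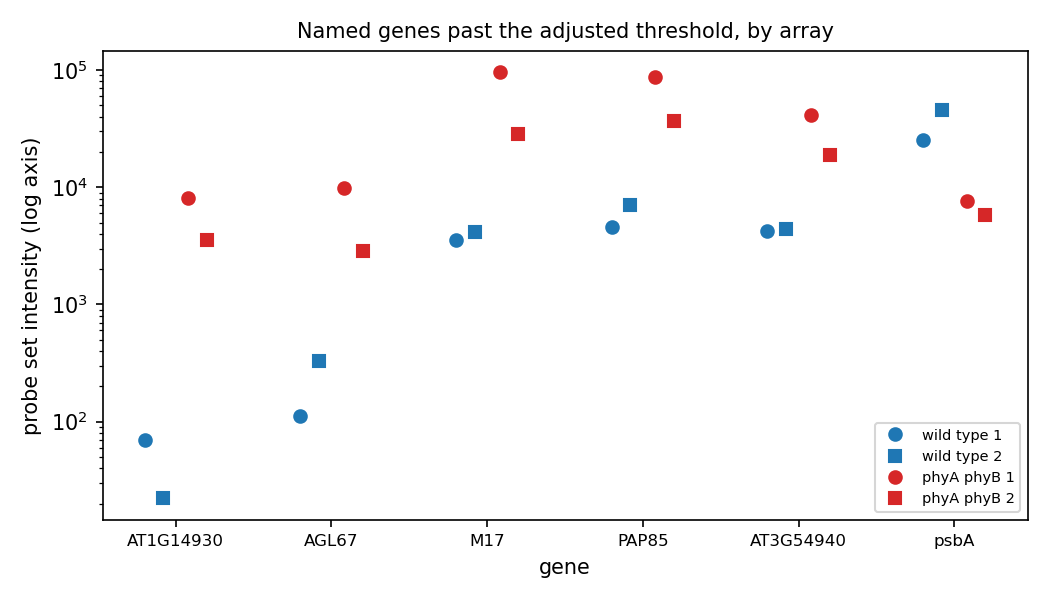
Deposited intensity of the 6 named genes past the adjusted threshold, on a log axis, with 1 point per array (blue, wild type; red, phyA phyB; circles, replicate 1; squares, replicate 2). Both mutant arrays lie above both wild-type arrays for 5 genes and below them for psbA.

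Over all probe sets tested, 13 passed an adjusted p of 0.05 in limma, 12 higher and 1 lower in the mutant. At an unadjusted p under 0.05 the count was 988, with 548 higher and 440 lower. At least 2-fold change without overlap between the groups was seen for 401 probe sets, 271 higher and 130 lower, and 4-fold change for 77, of which 71 were higher. The groups did not overlap for 38.3% of probe sets, where chance gives 33.3%. Of the 7 unnamed probe sets that passed, 248066_at rose by 3.81 and 253767_at by 3.32. The largest unnamed difference in the other direction was that of 264508_at, at -4.15 (adjusted p = 0.061, limma), with -2.91 on mutant array 1 and -5.39 on mutant array 2. Without mutant array 1 the count was 38 (31 higher, 7 lower) and 10 of the 13 were among them. Without mutant array 2 it was 422 (217 higher, 205 lower), and without wild-type array 1 or 2 it was 6 or 8.

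Among the lists fixed in advance, that of seed storage and oil body protein genes was the first with enough genes to test. All 5 tested members had higher means in the mutant, with a median log2 difference of 2.96. PAP85 rose at the threshold over all probe sets. Adjusted over the list alone, 4 rose: PAP85, the cupin gene AT2G28490 (3.33), the oleosin gene AT3G01570 (2.96) and AT1G03890 (1.06). OLEO3, an oleosin gene, differed by 0.23. The list rose as a whole (camera, adjusted p = 1.92e-08), and the adjusted p = 0.212 with an estimated correlation. The median was 3.92 on mutant array 1 and 2.01 on mutant array 2.

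LEA protein genes, whose products accumulate as seeds dry, had a median difference of 1.57 over 14 tested members. M17 rose over all probe sets, and 10 members rose when adjusted over the list alone. Among these were LEA (AT2G21490, 2.70) and AT3G53040 (2.23). The lowest values were those of AT3G02480 at 0.09 and AT4G36600 at -0.39. The list rose (camera, adjusted p = 4.99e-13), and the adjusted p = 0.296 with an estimated correlation. The median was 2.28 on mutant array 1 and 0.77 on mutant array 2.

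A list of other genes of the dry seed, picked as single genes rather than as a family, was chosen after the files had been seen. Its test was therefore not fixed in advance. All 14 members had higher means in the mutant, 12 of them without overlap, with a median of 1.81. AT3G54940 rose over all probe sets, and 10 members rose when adjusted over the list alone, among them AT1G65090 (2.89). BGLU19, a beta-glucosidase gene, differed by 1.62, with 2.71 on mutant array 1 and 0.54 on mutant array 2, and passed within this list but not within the list of beta-glucosidases (adjusted p = 0.134, limma). The list rose (camera, adjusted p = 5.23e-16), and the adjusted p = 0.558 with an estimated correlation. The median was 2.78 on mutant array 1 and 0.81 on mutant array 2. Of the remaining genes taken by the naming rule, AT1G54870 differed by 3.00 and AT1G27461 by 2.90, neither past the threshold.

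**Figure D2:**
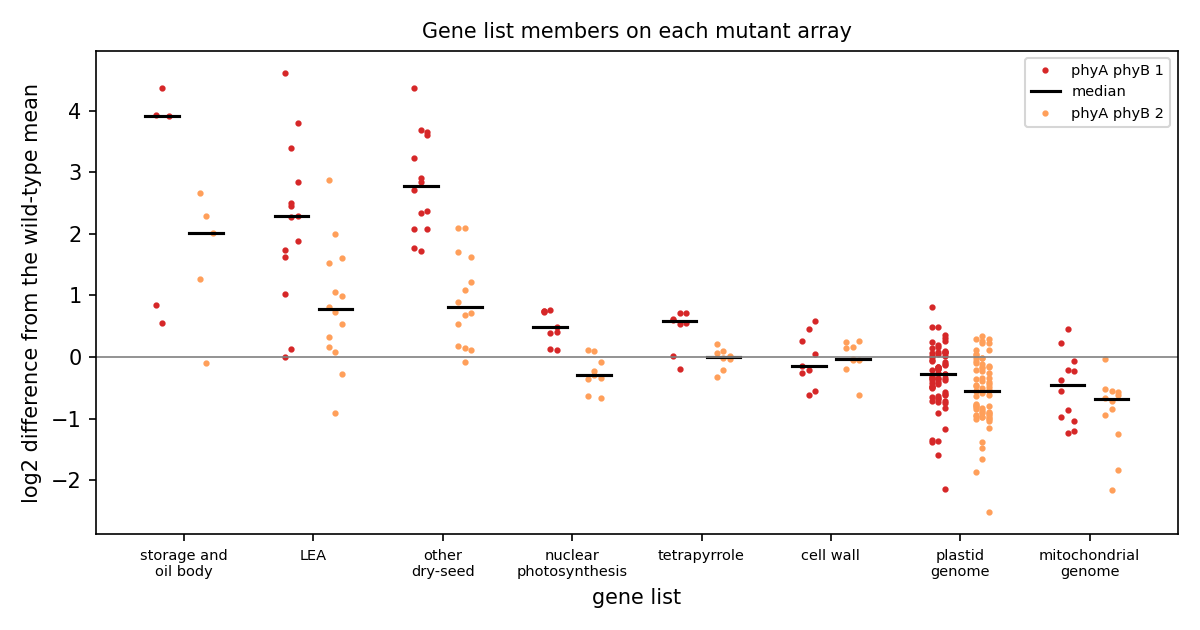
Log2 difference of each list member from the wild-type mean, on mutant array 1 (red) and mutant array 2 (orange), with black bars at the median. The medians of the seed storage list are 3.92 and 2.01, and those of the plastid genome list are -0.28 and -0.54.

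Genes of the plastid genome, a list also chosen after the files had been seen, were lower in the mutant, with a median difference of -0.41 over 69 genes. psbA fell over all probe sets. Adjusted over the list alone, 5 fell: psbA, psaJ (-1.53), ndhD (-1.62), psaC (-1.51) and matK (-1.16). The highest values were those of rpl36 at 0.43 and rps18 at 0.41. The list fell (camera, adjusted p = 4.14e-11), and the adjusted p = 0.647 with an estimated correlation. The plastid genes were higher on wild-type array 2 than on wild-type array 1 by a median of 0.77. Without wild-type array 1 the list's median was -0.735. Without wild-type array 2 it was -0.02 (camera, adjusted p = 0.574), and psbA was at -1.92 (limma, adjusted p = 0.21).

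The 12 tested genes of the mitochondrial genome had a median difference of -0.66. This list was chosen after the files had been seen and redefined after single genes had been seen. Its tests were therefore not fixed in advance. None fell over all probe sets (limma; 3 were lower at an unadjusted p under 0.05), and adjusted over the list alone cox1 (-1.52) and cox2 (-1.70), for subunits of cytochrome c oxidase, fell. The list fell (camera, adjusted p = 1.41e-05), and the adjusted p = 0.626 with an estimated correlation. These genes too were higher on wild-type array 2 than on wild-type array 1, by a median of 0.75. Without that array the list's median was -0.325 (camera, adjusted p = 0.0779), and without wild-type array 1 it was -1.05.

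The nuclear genes of photosynthesis, chlorophyll synthesis and cell wall loosening did not pass as lists. Only 9 of 49, 8 of 24 and 9 of 32 genes of these lists were tested. The results cover those genes and not the whole pathways. The 9 nuclear photosynthesis genes had a median difference of 0.08 (camera, adjusted p = 0.417), with RCA, the Rubisco activase gene, at 0.43 and LHCB4.2 at -0.27. The 8 tetrapyrrole genes had a median of 0.30 (adjusted p = 0.19, camera), with HEMB1 at 0.41 and CHLM at -0.20. The 9 cell wall genes had a median of -0.12 (adjusted p = 0.608, camera), with XTH19 at 0.25 and XTH33 at -0.33. In each of these lists 0 members passed in limma, over all probe sets or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The mutant arrays differed here. The photosynthesis median was 0.49 on mutant array 1 and -0.28 on mutant array 2, and the tetrapyrrole median was 0.58 and 0.00. Leaving out mutant array 1 or 2 gave the photosynthesis list an adjusted p of 0.00374 or 2.23e-04 (camera), in opposite directions, and leaving out mutant array 2 gave the tetrapyrrole list 0.00746.

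Of the 12 decreases taken by the naming rule, 5 were of genes in none of the lists. AT1G68490 differed by -1.33, AT5G26270 by -1.54, AT3G07350 by -1.09, AT1G43590 by -1.68 and AT1G22330 by -1.06. None of these passed (adjusted p from 0.0901 to 0.26, limma). Both mutant arrays lay below both wild-type arrays for each, which the naming rule required and which therefore adds no support.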

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

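The added gene lists were chosen after the files had been seen, and the other alternatives before. The count of 13 probe sets stayed within 1.5 times under quantile, median and cyclic loess normalization, both other pseudocounts, the brightest 40% and robust eBayes, at 9 to 16. It was 3 without a filter, where more probe sets were tested, 1 by eBayes without the trend, 31 at an adjusted p under 0.10, 248 at an unadjusted p under 0.01 and 401 by fold and overlap with no test. With each array left out it ran from 6 to 422, where the lone array was assumed to vary like the other group. Seed storage, LEA, dry-seed and plastid lists kept their calls and directions under the normalizations, pseudocounts and no filter. The adjusted p was 0.212, 0.296, 0.558 and 0.647 with an estimated correlation, 0.241, 0.371, 0.438 and 0.567 by directional fry, and 0.163, 0.233, 0.459 and 0.547 by mixed fry. With arrays left out, the adjusted p ran from 3.33e-34 to 0.574 for the plastid list, from 2.23e-04 to 0.597 for nuclear photosynthesis and from 0.00746 to 0.644 for tetrapyrrole genes. The cause was not tested for the last 2 lists. Over single named genes and alternatives, 1215 values stayed on their side of the threshold, 26 calls were lost, 28 gained and 0 reversed. Only the 6 called genes could lose a call or be counted as reversed, and each had 11 to 13 alternatives. The 26 losses and 0 reversals are therefore to be read against those alone. Changes of sign among the other named genes were not counted as reversals. Some occurred, as for PUB22, which kept its sign in 7 of 13 alternatives. Most of the 1215 values were of genes that did not pass in the main fit either. No paired analysis was possible because the groups shared fewer than 2 replicate numbers in the labels. Searches for the RY motif with their alternatives, and values for PHYA and PHYB, were not run. No signal over background was given, so low intensities limit what dim probe sets show.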

Other observations

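Some genes of lists too small to test are given as values, chosen after they were seen, none past the threshold over all probe sets. EEL, a bZIP gene of seed maturation, differed by 1.53, with 1.99 on mutant array 1 and 1.07 on mutant array 2, while BZIP53 and SPT differed by -0.34 and -0.50. LCR67, a plant defensin gene, differed by 2.02. FHL, which acts in the nuclear import of phytochrome A, differed by 0.81, with 0.86 and 0.76 on the mutant arrays. The 3 gibberellin receptor genes GID1A, GID1B and GID1C differed by -0.07, -0.08 and -0.16, in opposite directions on the mutant arrays. The 4 auxin genes tested had lower means, with WES1 at -0.52 and IAA29 at -0.16, the latter higher on mutant array 1, and ICL, for the glyoxylate cycle enzyme isocitrate lyase, differed by -0.04.

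Tubulin and ATG8 autophagy genes had lower means in all 7 members each, with medians of -0.34 and -0.25. Both lists had an adjusted p of 0.0494 (camera), and the adjusted p = 0.558 and 0.647 with an estimated correlation. Neither call held under cyclic loess (0.153 and 0.0726) or quantile normalization (0.0943 and 0.0713). With arrays left out, the tubulin call ended without wild-type array 1 (0.0692), wild-type array 2 (0.188) or mutant array 2 (0.121), and the ATG8 call without wild-type array 2 (0.3) or mutant array 1 (0.407). In limma 0 members passed, over all probe sets or within the list, and 0 had an unadjusted p under 0.05. Of the added lists not described so far, none had an adjusted p under 0.0679 (camera), which belonged to the TBL cell wall acetylation family at a median of -0.26. PUB19, a ubiquitin ligase gene, differed by -0.91 and was the member of its list that fell when adjusted over the list alone.

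The tests of the seed and plastid genes that follow were chosen after the results they bear on had been seen, although the scalings and the left-out arrays they use had been fixed before. The first pattern was the higher level of the 33 tested seed genes of the storage, LEA and dry-seed lists. Their lowest median over the deposited, quantile, median and loess scalings was 1.60. The median over all tested probe sets ran only from -0.0367 to 0.00476 under these scalings. A choice among them could hardly have removed the difference, so this outcome does not decide about scaling. On mutant array 2, 27 of 33 were above both wild-type arrays, with a median of 0.90 against 2.45 on array 1. Of the 33, 14 were picked after the files had been seen, and the genes vary together, so they are not separate observations. In the lists fixed in advance, 4 of 5 storage and 10 of 14 LEA genes were above both wild-type arrays on both mutant arrays. For these lists, that argues against mutant array 1 alone. Seeds that had not germinated, or late seedlings, in the mutant samples cannot be told apart from seed transcripts that persist within mutant seedlings, an untested biological explanation: the higher means of 32 of 33 genes restate the pattern, and the labels give no count of germinated seeds. Only 3 groupings of the 4 arrays exist, too few for a share under 0.05, with 13 calls for the genotypes and 0 as the highest of the others (limma; 373 and 349 at an unadjusted p under 0.05, against 988).

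The second pattern was the lower level of plastid genome genes. Dilution by seed RNA would lower the nuclear photosynthesis genes too. Their median of 0.0839 (bootstrap interval -0.08 to 0.43 over 9 genes) lay above the plastid median of -0.41. These 9 genes are not independent (estimated correlation 0.85), so the interval leaves out the spread between arrays. Their median was 0.49 on mutant array 1 and -0.28 on mutant array 2, so the comparison cannot decide about dilution. The test on nuclear photosynthesis genes replaced one between the mutant arrays, whose value had been seen, because that one compared single arrays. In it, 49 of 69 plastid genes were lower on mutant array 2 than on mutant array 1. The seed gene median was 0.90 on array 2 and 2.45 on array 1. As a comparison of single arrays, this does not decide about dilution either. A high plastid signal on wild-type array 2 may account for the fall of the list, since against wild-type array 1 only the median was -0.0214 (interval -0.19 to 0.11 over 69 genes, which are not independent). The mitochondrial genes were also higher on wild-type array 2, by 0.75 against 0.77, which is consistent with a common shift of RNA from both organelle genomes between arrays. Against wild-type array 1 only, psbA was at -1.92 and matK, the least of the 5 that fell within the list, at -0.88. These 5 were picked by their fall on the same arrays, so the values are no separate support. An effect of the genotype on these transcripts, of which psbA fell over all probe sets, was not tested apart from that choice and stays open.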
